A study of Rattus norvegicus with 14 samples.

How the data were processed

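Whole soleus muscle of male Sprague Dawley rats was measured on 14 Affymetrix arrays for the whole rat genome, 1 array per muscle. The muscles came from 12 rats. Tenotomy, in which the tendon is severed so that the muscle can no longer bear load, immobilized the muscle for 1, 2, 3, 4, 6, 16 or 22 weeks. Per the labels there were 4 control arrays, 6 arrays of short-term immobilized muscle (1 to 4 weeks) and 4 of long-term immobilized muscle (6 to 22 weeks). Rats 61 and 62 each gave a left muscle as control and a right muscle tenotomized for 6 weeks, so 2 rats gave 2 muscles. By the labels all controls were left muscles and all tenotomized muscles right ones. The controls came from rats 61, 62, 161 and 163, and the long-term arrays from rats 61, 62, 162 and 221. No rat gave both a short-term and a control array, and the labels give no age for the control muscles and no labelling or scanning date. A difference between cohorts of rats can therefore not be told apart from tenotomy in comparisons with short-term muscle.

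The authors' deposited values are probe set signals computed with MAS5, as a linear intensity with no log2 step. The scaling target, the software version and the detection calls are not stated. All 31099 probe sets held a value above 0 on each array, the highest being 12542. The arrays were not on a common scale: their medians ran from 29.7 to 49.1, which spans 0.73 on the log2 scale, and their trimmed means (2% trimmed) from 116 to 234. Arrays have no count depth, and their number limits the precision. No pair of arrays was identical, and the correlations between pairs of arrays lay between 0.85 and 0.94 for the deposited signals of all probe sets on the log2 scale, before the floor and filter.

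Signals were taken to log2. The rule fixed for scaling kept the deposited scale only if the array medians lay within 0.2 of each other, so each array was shifted to the common median. Values under the pooled 25th percentile (a signal of 9.69) were raised to it. The 57 control probe sets of the manufacturer were left out. Of the others, 20826 carried exactly 1 gene symbol, 436 carried several and 9780 none. The probe set with the highest mean log2 value stood for each of 14217 genes. A gene was tested if it lay above the pooled 40th percentile (a signal of 22.0) on at least 4 arrays, which left 11064 genes. Symbols were matched to the GRCr8 annotation for names only, and no position on a genome is given because the labels name no build.

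Groups were compared with limma 3.58.1 in R 4.3.3. All 14 arrays entered 1 fit with a mean per group, so that the groups shared 1 estimate of the spread, with an intensity trend in the variance. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. A trend over time was fitted as a slope on log2 of the week in the 10 tenotomized arrays. A second fit with a mean per time point compared 1, 2 and 6 weeks, each with 2 arrays, with the controls. Weeks 3, 4, 16 and 22 hold 1 array each and are given as values with no test. The p-values treat arrays as independent, although 2 rats gave an array to both the control and the long-term group.

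The scaling to a common median moved the median gene. Its log2 change was -0.34 for short-term against control, 0.02 for long-term against control and 0.37 for long-term against short-term. It was -0.33 at 1 week, -0.38 at 2 weeks and -0.04 at 6 weeks, and its slope was 0.12. All log2 changes of genes and lists are therefore given relative to the median gene of that comparison, while p-values and counts of calls refer to the scaled change before the subtraction. Each count was also taken under 4 other scalings: the deposited scale, a common 75th percentile, quantile normalization and a common 2% trimmed mean. Counts "under all 5 scalings" are genes past the threshold in the same direction in each of them.

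Gene lists were tested with camera in limma with a correlation between genes of 0.01, over 29 lists of at least 5 measured genes, with Benjamini-Hochberg adjustment over the lists. They hold contractile genes of slow and fast fibres, myogenic and developmental genes, the denervation response, atrophy ubiquitin ligases and autophagy, proteasome subunits, collagens and extracellular matrix, matrix proteases and inhibitors, growth factor signalling, stretch responsive genes, chaperones, the respiratory chain and ATP synthase, the tricarboxylic acid cycle, fatty acid oxidation and uptake, glycolysis and glycogen, polyamine and nitrogen metabolism, cytosolic ribosomal proteins, the cell cycle and the circadian clock. The others are markers of macrophages, lymphocytes and antigen presentation, mast cells and granulocytes, adipocytes, fibroblasts, tendon, endothelium, smooth muscle and pericytes, Schwann cells and nerve, and red blood cells. Each test was repeated with the correlation estimated per list and with fry, which asks whether the genes of a list move on balance in 1 direction and compares them with no other genes.

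The groups, comparisons, tests, filters, lists and the rule for named genes were fixed before the data were examined. The rule names, for each of the 3 group comparisons, the 8 largest rises and the 8 largest falls among genes past the threshold whose arrays do not overlap between the groups and which have, in each group, no more arrays at the floor than above it. It adds up to 2 further members of each list called, with the largest change in the direction of the list, and the 5 largest slopes in each direction for the trend. It always gives Myh7, Myh2, Myh1, Myh4, Myh3, Myh8, Fbxo32, Trim63, Myog, Chrna1, Ankrd2, Col1a1, Col3a1 and Adipoq. Other genes are named only where a small count falls outside the rule, and the text says so.

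The procedure was tested on simulated data of 11064 genes. With 100 genes changed by 2-fold and 100 by 4-fold, it recovered 60% and 98% of them in the short-term comparison, 59% and 96% in the long-term comparison and 61% and 94% between the tenotomized groups. At 1, 2 and 6 weeks it recovered 26%, 29% and 28% of the 2-fold changes and 79%, 86% and 75% of the 4-fold changes. For slopes of 0.5 and 1 on the log2 scale it recovered 84% and 99%. Signals of spike-in transcripts and ratios of 3' to 5' probe sets were compared between groups with exact 2-sided permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

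Alternatives were other floors, filters, scalings, rules for the probe set of a gene and variance models, array weights, the rat as a block, other sets of arrays and other models of time, and leaving out each array in turn. The deposited scale, the 2% trimmed mean, leaving out 2 doubted arrays (short-term replicate 4 and long-term replicate 4) and leaving out probe sets shared by several transcripts were added after the data were seen. Probe sets with no or several symbols were kept out of the comparisons, since they name no single gene.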

Results

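The data are 14 arrays of rat soleus, a slow postural muscle of the calf: 4 controls, 6 muscles tenotomized for 1 to 4 weeks and 4 tenotomized for 6 to 22 weeks. The first principal component held 56.7% of the variance and the second 8.67%. On the first component the 6 short-term arrays lay between -75.9 and -28.5, the 4 long-term arrays between 20.8 and 62.2 and the 4 controls between 33.6 and 41.6. The poly-A spike-ins, foreign transcripts added before labelling, read 268 ± 110 (SD, n = 6) on the short-term arrays, 108 ± 19.7 (n = 4) on the controls and 133 ± 27.4 (n = 4) on the long-term arrays. The short-term arrays differed from the controls in this with p = 0.019 (exact 2-sided permutation test), or 0.1 after adjustment over 21 such tests. The ratio of 3' to 5' probe sets of Gapdh, a measure of RNA quality, was 1.33 on the short-term arrays and 2.08 on the controls (p = 0.014, exact 2-sided permutation test), while that of actin went the other way, with 2.62 and 1.86 (p = 0.052, exact 2-sided permutation test). The distance of the 75th percentile from the median was 2.06 and 2.32 on the log2 scale (p = 0.0095, exact 2-sided permutation test). After adjustment these were 0.1 for Gapdh and the distance and 0.18 for actin. The hybridisation spike-ins read 902 ± 65.9, 929 ± 78.3 and 944 ± 125 in the same order of groups.

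The first comparison asks what differed from control muscle after 1 to 4 weeks without load, and no rat gave arrays to both groups. Genes of the extracellular matrix rose: 38 of the 40 measured members of the list of collagens and extracellular matrix were higher in short-term muscle, 33 of them under all 5 scalings, and the list median was 2.30 on the log2 scale. Markers of macrophages rose as well, with 14 of 20 higher and a median of 1.69. Genes of energy metabolism fell. In the list of fatty acid oxidation and uptake 24 of 25 were lower (median -1.02), in the tricarboxylic acid cycle 15 of 16 (median -0.70) and in the respiratory chain and ATP synthase 69 of 71 (median -0.45). In all, 5745 of 11064 genes passed the threshold. Changes are printed relative to the median gene, while each gene's p-value tests the scaled change before that subtraction.

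Among genes without overlap and above the floor as the fixed rule asks, the largest rises included several secreted proteins of connective tissue. Cthrc1, a secreted protein linked to collagen deposition, had a geometric mean signal of 24.3 in control muscle and 1123 in short-term muscle, a log2 change of 5.88 (SE 0.59, n = 6 and 4, adjusted p = 7.5e-06). Spon1, an extracellular matrix glycoprotein, rose by 5.05 (SE 0.38, adjusted p = 2.2e-06) and C1qtnf3 by 4.61 (SE 0.48, adjusted p = 1.1e-05). Igsf10 rose by 4.44, Cxcl13, a chemokine that attracts B lymphocytes, by 4.32, Pamr1 by 4.23, P4ha3, a subunit of the enzyme that hydroxylates proline in collagen, by 4.12 and Cpxm1 by 4.07. Each of these 8 genes was higher on all 6 short-term arrays than on any of the 4 controls, and 1 or 2 control arrays lay at the floor for Cxcl13, P4ha3 and Cpxm1. The control signals of these 3 genes (17.4, 17.0 and 15.6), of Igsf10 (21.7) and of Pamr1 (21.0) lay under the filter signal of 22.0, so their sizes and order depend on dim control values.

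Among genes without overlap between the arrays of both groups, the largest falls were led by Aqp7, a channel for water and glycerol, whose signal was 715 in control and 55.3 in short-term muscle, a log2 change of -3.35 (SE 0.31, adjusted p = 2.2e-06). LOC102554789 changed by -2.91 (SE 0.37, adjusted p = 1.2e-05), Phf24 by -2.78, Reep6 by -2.71 and Padi2, an enzyme that turns arginine of proteins into citrulline, by -2.60. LOC100912310 changed by -2.49, Stbd1, a protein that binds glycogen, by -2.43 and Pik3c2g, a lipid kinase, by -2.38. All 8 were lower on each of the 6 short-term arrays than on any control, and LOC102554789 lay at the floor on 3 short-term arrays and Phf24 on 1.

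Within the matrix list, Col8a1 rose by 3.93 (SE 0.53, adjusted p = 6.3e-05), Postn (periostin) by 3.82 (SE 0.60, adjusted p = 2.3e-04), and Col1a1 and Col3a1, which encode chains of the fibrillar collagens, by 3.09 and 1.76. Camera gave this list an adjusted p = 8.3e-25, and an adjusted p = 0.28 with an estimated correlation. Of 14 matrix proteases and inhibitors 8 were higher (median 1.55, adjusted p = 1.7e-05, and adjusted p = 0.30 with an estimated correlation), led by Mmp14, a membrane-bound collagenase, at 3.46 and Ctsk, a lysosomal protease that degrades collagen, at 3.34. The single member that fell was Timp4, an inhibitor of matrix proteases, at -1.01, named after its value was seen. Of 13 fibroblast markers 8 rose (median 1.53, adjusted p = 4.5e-06, and adjusted p = 0.36 with an estimated correlation), with Thy1 at 3.53 and Serping1 at 1.94. Of 8 tendon markers 4 rose (median 1.26, adjusted p = 0.0055, and adjusted p = 0.46 with an estimated correlation), with Tnc at 3.21 and Tnmd, a membrane protein of tendon cells, at 2.36. The Tnmd call was lost without short-term replicate 4 (adjusted p = 0.052), control replicate 1 (0.050) or control replicate 2 (0.075).

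In growth factor signalling 7 of 20 rose and 2 fell (median 0.65, adjusted p = 0.0011, and adjusted p = 0.28 with an estimated correlation). Igf1, a growth factor for muscle, rose by 2.58 (SE 0.44, adjusted p = 6.7e-04) and Tgfb1, a growth factor that stimulates matrix production, by 2.35 (SE 0.44, adjusted p = 0.00145), with 2 control arrays at the floor. The members that fell, Akt1 at -0.56 and Akt2 at -0.25, were named after their values were seen, and neither was lower under all 5 scalings.

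Markers of macrophages and of lymphocytes and antigen presentation were called higher as well, while those of mast cells and granulocytes were not. The macrophage list had an adjusted p = 1.3e-11, and an adjusted p = 0.30 with an estimated correlation. Fcer1g, an adaptor of receptors for immunoglobulin, rose by 2.29 (SE 0.29, adjusted p = 6.2e-05) and Cd68, a lysosomal protein of macrophages, by 2.28 (SE 0.33, adjusted p = 1.9e-04). Of 12 lymphocyte and antigen presentation markers 7 rose and 1 fell (median 1.64, adjusted p = 1.8e-06, and adjusted p = 0.28 with an estimated correlation). RT1-Ba and RT1-Db1, which encode class II histocompatibility chains, rose by 3.49 and 2.59. Another probe set of RT1-Ba gave 0.32 (adjusted p = 0.96) and another of RT1-Db1 1.52 (adjusted p = 0.12). RT1-Bb, another chain of class II, was lower by -1.98, with 4 short-term arrays at the floor and a call kept under 2 of the 5 scalings, and another probe set of it gave 0.65 (adjusted p = 0.71). Cell cycle genes rose too, 10 of 21 (median 0.93, adjusted p = 7.9e-06, and adjusted p = 0.34 with an estimated correlation), 7 of them under all 5 scalings. Among these were Cks2 at 2.36 and Top2a, which untangles replicated DNA, at 2.05, where another probe set gave 0.99 (adjusted p = 0.17). Both genes were dim, so these sizes depend on low signals. On the log2 scale Cks2 read 3.44 to 4.67 on the controls, and the mean of Top2a over all arrays was 4.76. Schwann cell and nerve markers rose in 3 of 8 (median 0.78, adjusted p = 0.045, and adjusted p = 0.49 with an estimated correlation), but in 0 when adjusted over the list alone. Mbp, a myelin protein, had a change of 1.75 (adjusted p = 0.025) and S100b 1.29 (adjusted p = 0.043). The list call was lost without short-term replicate 3 (adjusted p = 0.068), 4 (0.051) or 5 (0.059) and after quantile normalization (0.082). The call of Mbp was lost without any of 6 single arrays (up to 0.065) and that of S100b without any of 8 (up to 0.13).

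In energy metabolism, 23 of the 24 fatty acid oxidation genes that fell did so under all 5 scalings, and camera gave adjusted p = 4.0e-09, and adjusted p = 0.30 with an estimated correlation. Ppargc1a, a coactivator that drives mitochondrial gene expression, fell by 1.98 (SE 0.44, adjusted p = 4.4e-04), or by 1.28 without control replicate 3 (adjusted p = 1.4e-04), and Hadh, a dehydrogenase of beta oxidation, by 1.74 (SE 0.17, adjusted p = 2.2e-06). For the respiratory chain the adjusted p = 3.1e-12, and adjusted p = 0.46 with an estimated correlation, with 41 members lower under all 5 scalings. Ndufs1 and Ndufb8, subunits of complex I, fell by 1.69 and 1.63. For the tricarboxylic acid cycle the adjusted p = 1.8e-06, and adjusted p = 0.39 with an estimated correlation. Here 13 members fell under all 5 scalings and 16 when adjusted over the list alone, among them Pdhx, a part of pyruvate dehydrogenase, by 1.52 and Suclg1 by 1.09. Glycolysis and glycogen genes fell in 19 of 25 and rose in 1, 8 lower under all 5 scalings (median -0.27, adjusted p = 0.0070, and adjusted p = 0.59 with an estimated correlation). Phka1, a subunit of phosphorylase kinase, fell by 1.12 and Fbp2, the muscle fructose bisphosphatase, by 0.90 (adjusted p = 0.021), a call lost without control replicate 1 (0.052) or 2 (0.054) and under 2 of the 5 scalings. The glycolysis call was lost after quantile normalization (0.082). The member that rose, Hk1 at 0.91, was not higher under all 5 scalings and was named after its value was seen. Chaperones fell in 19 of 28, 8 under all 5 scalings (median -0.27, adjusted p = 0.028, and adjusted p = 0.71 with an estimated correlation), with Hspa9 of mitochondria at -1.37, where 1 of its 4 probe sets gave 1.02 (adjusted p = 0.505), and Hspb3, a small heat shock protein, at -1.06. The chaperone call was lost without short-term replicate 1 (0.054) or control replicate 3 (0.071) and after quantile normalization (0.56). Proteasome subunits were lower in 24 of 33 and in 27 when adjusted over the list alone (median -0.18, adjusted p = 0.0070, and adjusted p = 0.71 with an estimated correlation), but none was lower under all 5 scalings and quantile normalization turned the median to 0.03. The proteasome median was -0.10 without short-term replicate 6. Psmd12 had a change of -0.50 (adjusted p = 0.0024) and Psmb2 -0.39 (adjusted p = 0.0013), both lost under quantile normalization.

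Among contractile genes, Myh7, the slow myosin heavy chain of soleus, had a change of 0.17 relative to the median gene (SE 0.16) and of -0.17 as tested (adjusted p = 0.38; relative change 0.09 without control replicate 4), with signals of 10680 in control and 9495 in short-term muscle. In the fast fibre list 5 of 15 rose and 2 fell (median 1.31, adjusted p = 0.0055, and adjusted p = 0.46 with an estimated correlation), and 2 rose and 1 fell when adjusted over the list alone. The list median was 0.84 without control replicate 3 and 0.82 without control replicate 4. Myh4, the heavy chain of the fastest fibres, rose by 2.87 (SE 0.66, adjusted p = 0.0046), from a signal of 38.1 to 219. Tnnt3, fast troponin T, had a change of 2.12 (SE 0.72, adjusted p = 0.049), and another probe set of it 0.18 (adjusted p = 0.87). Myh1, another fast heavy chain, fell by 1.21 (SE 0.18, adjusted p = 1.3e-05) on the probe set used, while of its 4 other probe sets 1 gave 0.08 (adjusted p = 0.35) and 3 lay between -1.54 and -0.82. Myh2, the heavy chain of fast oxidative fibres, had a change of 1.67 (SE 0.57, adjusted p = 0.060), which passed under the 4 other scalings and without control replicate 1 (2.20, adjusted p = 0.012), control replicate 2 (2.27, 0.0099) or short-term replicate 1 (1.83, 0.048), and was 0.98 without control replicate 4 (0.29). On the log2 scale Myh2 read 10.05 on control replicate 3 and 9.24 on control replicate 4 but about 13 on the other controls, and Tnnt3 read 8.78 and 7.36 on these arrays. The Tnnt3 call was lost without 1 array for 12 of the 14 arrays, reaching adjusted p = 0.24 without control replicate 4 and 0.18 without control replicate 3.

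Heavy chains of developing muscle were higher. Myh3, the embryonic form, rose by 2.28 (SE 0.47, adjusted p = 0.0027), and Myh8, the perinatal form, was at least 3.70-fold higher (adjusted p = 0.0019), since its control signals lay near the floor. Their list, myogenic and developmental genes, had 5 of 11 higher and 2 lower but was not past the threshold (median 1.08, adjusted p = 0.060; median 0.49 without control replicate 3), and Myog had a change of 0.00 relative to the median gene and of -0.34 as tested (adjusted p = 0.055). Of the ligases of atrophy, Fbxo32 had a change of -0.09 over the 6 arrays (SE 0.48, adjusted p = 0.46), with 1.20 at 1 week (SE 0.41, adjusted p = 0.12) and -1.02 at 2 weeks (adjusted p = 0.016, lost under 2 of the 5 scalings). Trim63 had a change of -0.66 (SE 0.34, adjusted p = 0.020), a call lost without control replicate 3 (adjusted p = 0.085) and under 3 of the scalings. In their list 8 of 20 were lower and 1 higher, of which 1 and 1 under all 5 scalings (median -0.09, adjusted p = 0.67), and its mean was 0.44 at 1 week and -0.07 at 2 weeks. Chrna1, a subunit of the acetylcholine receptor, had a change of -0.54 (SE 0.34, adjusted p = 0.038), lost under all 4 other scalings and without any of 7 single arrays (-0.32 without short-term replicate 5, adjusted p up to 0.12). In the denervation response 2 of 11 were higher and 3 lower, of which 2 and 0 under all 5 scalings (median 0.23, adjusted p = 0.36). Its median lay between -0.02 without control replicate 2 and 0.48 without control replicate 4. Ankrd2 had a change of -0.38 (adjusted p = 0.073), or -0.07 without short-term replicate 1, and Adipoq of 1.02 (adjusted p = 0.25).

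Further lists did not pass. Slow fibre genes were lower in 5 of 11, 2 of them under all 5 scalings, with a median of 0.03, a mean of -0.18 and a test that pointed down (adjusted p = 0.24). Stretch responsive genes were lower in 8 of 22 and higher in 1, 0 and 1 under all 5 scalings, with a median of 0.03 and a test that pointed down (adjusted p = 0.61). Polyamine and nitrogen metabolism had 2 of 14 higher and 8 lower, 2 and 2 under all 5 scalings (median -0.21, or -0.10 without short-term replicate 6, adjusted p = 0.48), and the circadian clock 6 of 15 lower, 2 under all 5 scalings (median -0.10, adjusted p = 0.71). Cytosolic ribosomal proteins had 2 of 39 higher and 11 lower, 1 and 0 under all 5 scalings, with a median of 0.09 and a test that pointed down (adjusted p = 0.53). Adipocyte markers had 5 of 19 higher and 7 lower, 4 and 3 under all 5 scalings (median 0.89, or 0.37 without short-term replicate 3, adjusted p = 0.21), endothelial markers 1 of 13 each way (median 0.31, adjusted p = 0.24), and smooth muscle and pericyte markers 3 of 12 higher and 1 lower, 2 and 0 under all 5 scalings (median 0.50, adjusted p = 0.053). Of 7 mast cell and granulocyte markers and 5 red blood cell markers 0 passed in limma (medians 0.08 and 0.27, adjusted p = 0.36 and 0.24), and the red blood cell median lay between 0.14 without short-term replicate 4 and 0.51 without short-term replicate 3. Fry, which compares a list with no other genes, called 17 of the 29 lists, and camera with an estimated correlation 0, with 4 at an unadjusted p under 0.05.

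By limma 1362 genes were higher and 4383 lower in short-term muscle, but the balance moved with the scaling: 2080 and 2800 at a common 75th percentile, 2026 and 2459 after quantile normalization, 1103 and 3234 as deposited, and 2584 and 2015 at a common trimmed mean. Under all 5 scalings 1079 genes were higher and 1843 lower, and by at least 2-fold relative to the median gene 1214 were higher and 471 lower. The groups did not overlap in 3994 genes (36.1%, against 0.95% by chance).

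**Figure D1:**
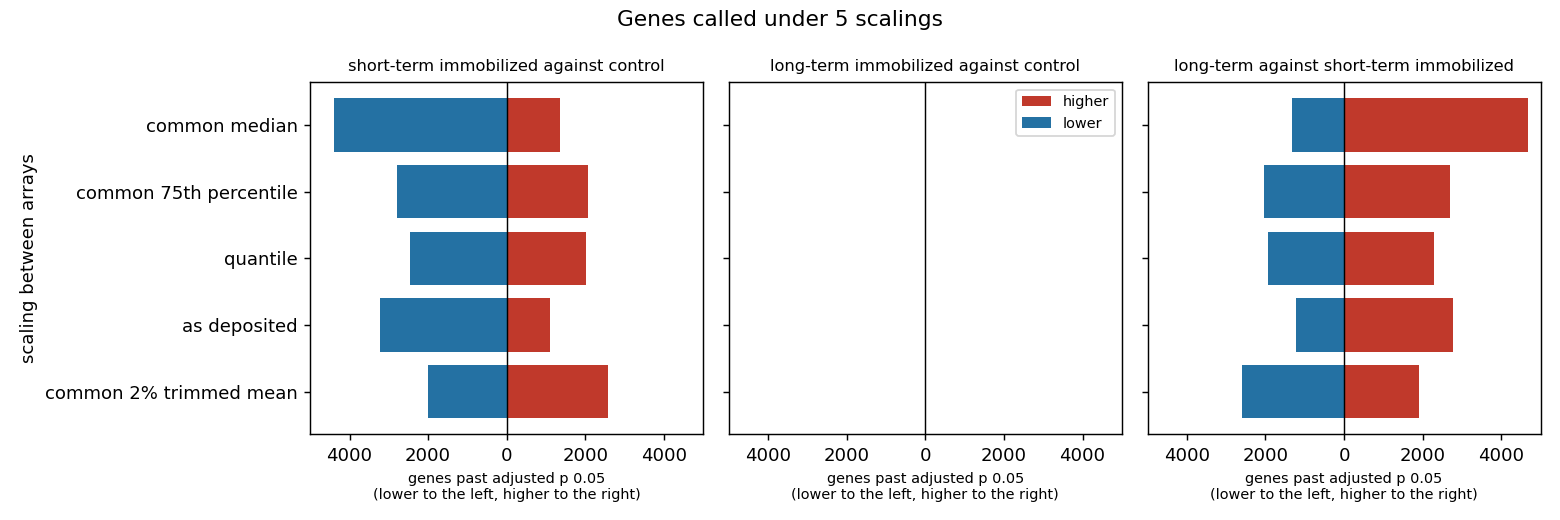
Genes past an adjusted p of 0.05 under 5 scalings between arrays, for each of the 3 group comparisons. Bars to the right count genes that were higher and bars to the left genes that were lower, with 1362 and 4383 for short-term against control at a common median and 0 for long-term against control under each scaling.

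The second comparison asks what differed from control muscle after 6 to 22 weeks. No gene passed the threshold in limma: 0 of 11064, with 218 at an unadjusted p under 0.05 where 553 would be due to chance and the smallest adjusted p at 1. A count below that of chance does not show that no gene changed. The fit shared its spread with the short-term arrays and ignored that 2 rats gave both muscles, which can make the test too cautious. For the groups of genes that had moved in short-term muscle, the list median over the 4 arrays was -0.08 for collagens and extracellular matrix, -0.19 for macrophage markers, -0.01 for fatty acid oxidation and 0.03 for the respiratory chain. The medians of matrix and macrophage genes pool opposite values: the matrix mean was 0.47 at 6 weeks and -1.26 at 22 weeks, and the macrophage mean 0.27 and -1.27. The 22-week values come from 1 array, whose 3' to 5' ratios were the highest of the long-term arrays. They were 2.78 for Gapdh and 3.74 for actin, where the other long-term arrays had 1.39 to 2.15 for actin. Whether its quality bears on the low values was not tested. Without long-term replicate 4, the 22-week array, the matrix median was 0.24 (adjusted p = 3.2e-06). Cthrc1 had a signal of 26.3 in long-term muscle and 24.3 in control, and Aqp7 626 and 715. The signal of Cthrc1 pools opposite values too, with 0.99 against control at 6 weeks, -0.13 at 16 and -1.53 at 22 weeks on the log2 scale. In the simulated data 96% of 4-fold and 59% of 2-fold changes were found at this group size, and no smaller change was simulated.

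Of the genes always given none passed the threshold, and the largest values were those of Myh2 and the developmental heavy chains: Myh2 1.57 (SE 0.63), which was 0.88 without control replicate 4, and Myh3 1.55 (SE 0.51), with Myh8 at least 1.33-fold, since all 4 of its control signals lay under the filter. The other such genes lay between -0.47 for Chrna1 (-0.29 without control replicate 4) and 0.39 for Myog, with Myh7 at 0.07, Myh1 at 0.00, Myh4 at -0.31 (from -0.77 without long-term replicate 3 to 0.05 without replicate 2), Col1a1 at -0.41 (from -0.87 without long-term replicate 2 to 0.22 without replicate 4), Col3a1 at -0.02, Fbxo32 at 0.14, Trim63 at -0.20, Ankrd2 at 0.26 and Adipoq at 0.23, each with an adjusted p = 1. The last 4 values moved as single arrays were left out: Fbxo32 from -0.01 (control replicate 1) to 0.36 (control replicate 2), Trim63 from -0.32 (long-term replicate 3) to 0.02 (control replicate 3), Ankrd2 from 0.07 (control replicate 2) to 0.41 (control replicate 3) and Adipoq from 0.04 (long-term replicate 2) to 0.70 (long-term replicate 4).

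Camera called 3 lists, none of whose members passed alone, and fry called 0. Myogenic and developmental genes were higher (11 genes, median 0.33, adjusted p = 0.014), fast fibre genes higher (15 genes, median 0.16, adjusted p = 0.017) and tendon markers lower (8 genes, median -0.53, adjusted p = 0.017). Each of the 3 had an adjusted p = 0.99 with an estimated correlation. The fast fibre median ranged from 0.08 without control replicate 4 to 0.49 without control replicate 2, and its call was lost without long-term replicate 3 (adjusted p = 0.33), control replicate 3 (0.12) or control replicate 4 (0.80). The tendon call was lost without control replicate 4 (0.17), and without long-term replicate 4, the 22-week array, the tendon list gave -0.03 and adjusted p = 0.75, while it was -0.96 without replicate 1. The myogenic median was 0.19 without replicate 4. Without that array the matrix list turned to 0.24 (adjusted p = 3e-06) and the macrophage list to 0.18 (adjusted p = 0.049). The number of lists called ranged from 2 to 12 as single arrays were left out, 12 without long-term replicate 2 and 9 without replicate 1, the 6-week arrays. With the 2 rats that gave both muscles as a fixed block (2 pairs), 2 genes and 10 lists were called, and with the rat as a random block over all arrays 0 genes and 3 lists.

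The remaining 26 lists had an adjusted p of 0.071 or more, the nearest to the threshold being matrix proteases (median -0.18) and macrophage markers, each at 0.071, followed by the circadian clock (median 0.23) at 0.15. Matrix proteases were called without long-term replicate 1 (-0.32, adjusted p = 0.0018) or 2 (-0.33, adjusted p = 5.1e-04) and stood at 0.17 without replicate 4, where the clock stood at 0.03. Macrophage markers were called at -0.48 without replicate 2 (adjusted p = 5.0e-07) and at -0.36 without control replicate 4 (adjusted p = 0.0066).

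The third comparison sets long-term against short-term muscle and is also the test of whether the changes against control differ between both. Matrix genes and markers of macrophages and lymphocytes were lower and genes of energy metabolism higher in long-term muscle. Of 40 collagens and matrix genes 38 were lower (median -2.30), of 20 macrophage markers 16 (median -1.89), while 24 of 25 fatty acid oxidation genes (median 0.96) and 69 of 71 respiratory chain genes (median 0.47) were higher. In limma 6028 of 11064 genes passed.

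The largest rise was that of Gnat3, a subunit of the G protein of taste cells, at 4.64 (SE 0.82, n = 4 and 6, adjusted p = 1.5e-04), with signals of 25.7 in short-term and 831 in long-term muscle and 652 in control. Its size depends on the floor, where 2 of the 6 short-term arrays lay, and 4 lay under the filter signal. Aqp7 rose by 3.13 (SE 0.31, adjusted p = 5.1e-06), LOC102554789 by 2.89, Fam216b by 2.79, Pik3c2g by 2.57, G0s2, an inhibitor of the lipase that releases fatty acids, by 2.48, Amy1, an amylase, by 2.41 and Rbm44 by 2.32. Under the same rule on overlap and floor, which leaves out Tnn, the largest falls were Cthrc1 at -5.79 (SE 0.59, adjusted p = 1.2e-05), RT1-Ba at -4.84, where another probe set gave -0.66 (adjusted p = 0.54), and Spon1 at -4.83, followed by C1qtnf3 at -4.65, Cxcl13 at -4.63, Lbp, which binds bacterial lipopolysaccharide, at -4.38, Pamr1 at -4.16 and Col8a1 at -4.15. These 16 genes had no overlap between the 6 short-term and the 4 long-term arrays.

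Of the matrix list, 35 members were lower under all 5 scalings and 39 when adjusted over the list alone (adjusted p = 5e-27, and adjusted p = 0.19 with an estimated correlation), with Postn at -4.07, Tnc at -3.67, Col1a1 at -3.51 and Col3a1 at -1.79. Matrix proteases were lower in 9 of 14 (median -1.61, adjusted p = 4.8e-07, and adjusted p = 0.19 with an estimated correlation), with Mmp14 at -3.51 and Ctsk at -3.40. Timp4, higher at 0.82, was named after its value was seen. Growth factor signalling was lower in 7 of 20 and higher in 3 (median -0.67, adjusted p = 0.0022, and adjusted p = 0.19 with an estimated correlation), with Igf1 at -2.59 and Igfbp4 at -2.34. The members that rose, named after their values were seen, were Acvr2b at 0.24, Akt1 at 0.68 and Akt2 at 0.22, with 1 of them higher under all 5 scalings. Fibroblast markers were lower in 9 of 13 (median -1.39, adjusted p = 4.8e-07, and adjusted p = 0.27 with an estimated correlation), with Thy1 at -3.72 and Pdgfrl at -2.35. Tendon markers were lower in 5 of 8 (median -1.92, adjusted p = 1.6e-04, and adjusted p = 0.33 with an estimated correlation), with Comp, a protein of cartilage and tendon matrix, at -2.97 and Tnmd at -2.81.

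Macrophage markers had an adjusted p = 9.6e-14, and adjusted p = 0.19 with an estimated correlation. Aif1 was lower by -2.54 and Adgre1, a surface receptor of macrophages, by -2.37. The Aif1 call rests on a probe set shared by transcripts and was lost without such probe sets (-0.46, adjusted p = 0.83). Lymphocyte and antigen presentation markers were lower in 8 of 12 and higher in 1 (median -1.71, adjusted p = 6.9e-07, and adjusted p = 0.19 with an estimated correlation), with Cd74, the invariant chain of class II, at -2.60 and RT1-Db1 at -2.74, a call lost in the same way (-1.03, adjusted p = 0.38). The member that rose was RT1-Bb at 2.61, where another probe set gave -1.59 (adjusted p = 0.12). Cell cycle genes were lower in 11 of 21 and higher in 1 (median -1.16, adjusted p = 5.4e-07, and adjusted p = 0.27 with an estimated correlation), with Cks2 at -2.53 and Mki67, a marker of dividing cells, at -2.38. Bub1, the member that rose, stood at 0.37, was not higher under all 5 scalings and was named after its value was seen. The Schwann cell list was lower with 1 of 8 members past the threshold and 0 when adjusted over the list alone (median -0.76, adjusted p = 0.015, and adjusted p = 0.43 with an estimated correlation). That member was Pmp22 at -0.998 (adjusted p = 0.028), a call lost without short-term replicates 4, 5 or 6 or long-term replicates 3 or 4 (adjusted p from 0.052 to 0.089).

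Among the lists that rose, the respiratory chain had 43 members higher under all 5 scalings and 70 when adjusted over the list alone (adjusted p = 2e-13, and adjusted p = 0.43 with an estimated correlation), with Ndufs1 at 1.72 and Ndufa5 at 1.598. Fatty acid oxidation had 23 higher under all 5 scalings (adjusted p = 9.7e-09, and adjusted p = 0.27 with an estimated correlation), with Hadh at 1.59 and Acaa2, a thiolase of beta oxidation, at 1.52. The tricarboxylic acid cycle had 15 of 16 higher, 13 under all 5 scalings (median 0.69, adjusted p = 1.4e-06, and adjusted p = 0.36 with an estimated correlation), with Pdhx at 1.34. Glycolysis and glycogen had 20 of 25 higher, 8 under all 5 scalings, and Hk1 lower at -0.89 (median 0.32, adjusted p = 0.0036, and adjusted p = 0.60 with an estimated correlation), with Hk2 at 0.97 (adjusted p = 0.020), a call lost without long-term replicate 2 (0.60, adjusted p = 0.083), and Phka1 at 0.87. The Hk2 change was 0.60 without short-term replicate 4 as well, and its call held under 1 of the 5 scalings. The glycolysis median was 0.49 without short-term replicate 3, and Hk1 was not lower under all 5 scalings. Chaperones were higher in 19 of 28, 6 under all 5 scalings (median 0.24, adjusted p = 0.015, and adjusted p = 0.60 with an estimated correlation), with Hspa9 at 1.14 and Hspb3 at 1.12. Proteasome subunits were higher in 28 of 33 but none under all 5 scalings (median 0.22, adjusted p = 0.0042, and adjusted p = 0.60 with an estimated correlation), with Psmd12 at 0.49 and Psmd1 at 0.38 (0.22 without long-term replicate 4), and quantile normalization turned the median to -0.03. After quantile normalization the calls of chaperones (adjusted p = 0.57), glycolysis (0.072) and Schwann cell markers (0.072) were lost too. Of the 14 lists not called, fast fibre genes (4 of 15 lower and 2 higher), smooth muscle and pericyte markers (1 of 12 higher) and slow fibre genes (8 of 11 higher) lay nearest to the threshold, each with adjusted p = 0.11.

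Of the contractile genes Myh1 was higher by 1.20 (SE 0.18, adjusted p = 1.5e-05), with 1 of its probe sets at -0.64 (adjusted p = 0.35), and Myh4 lower by -3.18 (SE 0.66, adjusted p = 0.0022). Relative to the median gene Myh7 and Myh2 each differed by -0.11, but as tested both by 0.26 (adjusted p = 0.17 and 0.71). Myh3 differed by -0.74 (adjusted p = 0.53), or -0.32 without long-term replicate 3, and Myh8 by -1.85 (adjusted p = 0.072). Myog was higher by 0.38 (adjusted p = 5.0e-04), lost under quantile normalization, Ankrd2 by 0.63 (adjusted p = 0.016; 0.31 without short-term replicate 1), lost under 3 of the scalings and without long-term replicate 4 (adjusted p = 0.051), and Trim63 by 0.46 (adjusted p = 0.046), lost under all 4 other scalings and without any of 10 single arrays (0.25 without short-term replicate 6). Fbxo32 differed by 0.21 (adjusted p = 0.31; -0.14 without short-term replicate 4 and 0.49 without short-term replicate 1), Chrna1 by 0.06 (adjusted p = 0.29) and Adipoq by -0.80 (adjusted p = 0.47), or -0.31 without long-term replicate 4.

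By limma 4693 genes were higher and 1335 lower in long-term muscle. The balance again moved with the scaling: 2705 and 2050 at a common 75th percentile, 2284 and 1940 after quantile normalization, 2772 and 1215 as deposited, and 1895 and 2590 at a common trimmed mean. Under all 5 scalings 1698 genes were higher and 1172 lower. Fry called 18 of the 29 lists against 15 by camera, and camera with an estimated correlation 0, with 5 at an unadjusted p under 0.05.

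**Figure D2:**
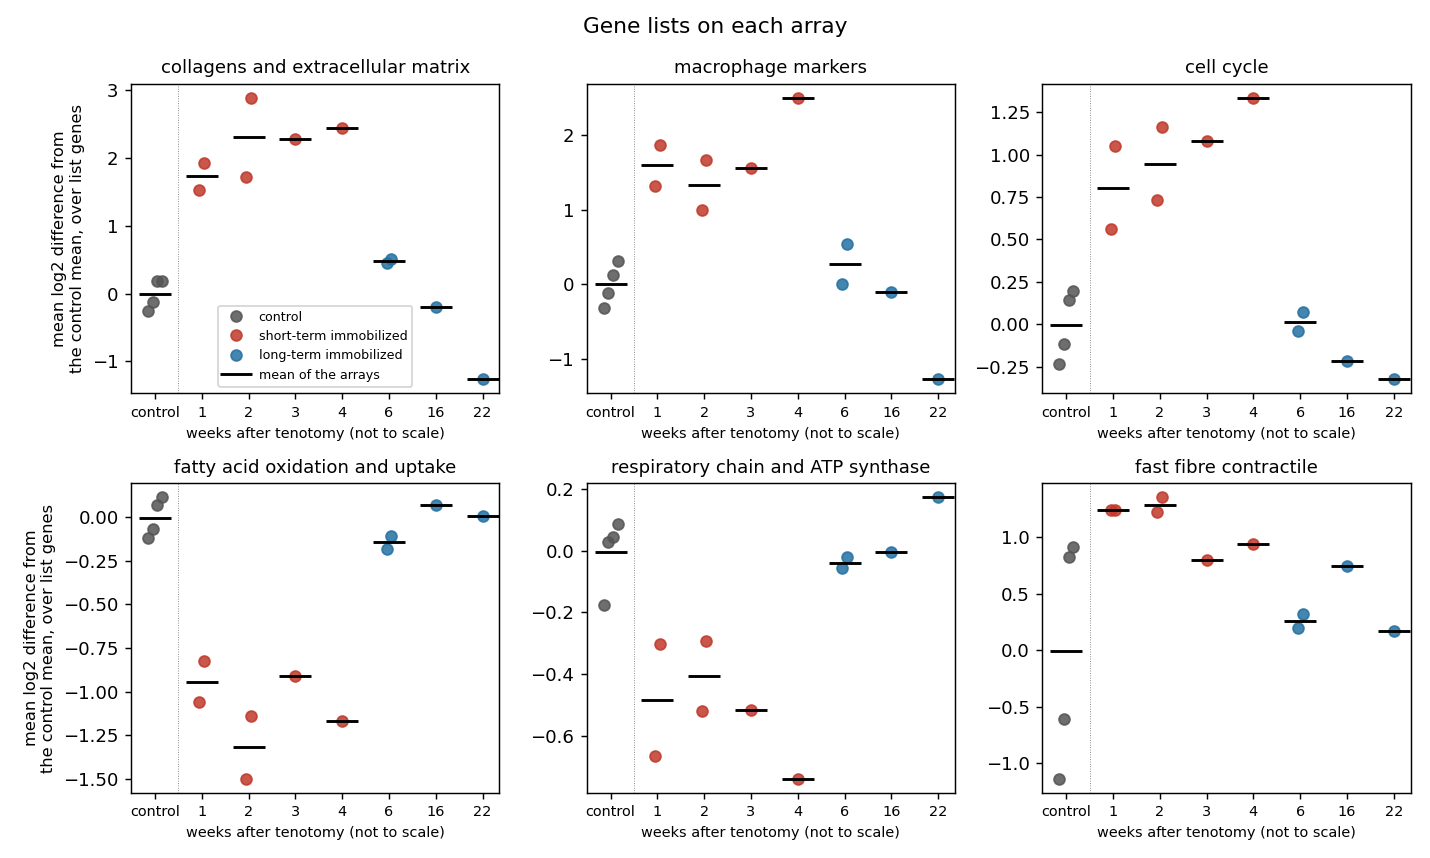
Mean log2 difference from the control mean over the genes of 6 lists, for each array, against weeks after tenotomy (not to scale). Points are arrays, coloured by group, and black bars are means of the arrays of a time point: collagens and extracellular matrix lay at 1.73 to 2.45 from 1 to 4 weeks and at 0.47, -0.20 and -1.26 at 6, 16 and 22 weeks. Weeks 16 and 22 hold 1 array each.

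The series is a time course over 7 time points. Weeks 3, 4, 16 and 22 hold 1 array each, and the 22-week array stood apart in its 3' to 5' ratio of Gapdh (2.78). Its values can therefore not be told apart from a difference in RNA quality. The mean of the matrix list over the arrays of a week was 1.73 at 1 week, 2.31 at 2, 2.29 at 3, 2.45 at 4, 0.47 at 6, -0.20 at 16 and -1.26 at 22 weeks, with an SD between controls of 0.22. Macrophage markers read 1.597, 1.33, 1.56, 2.504, 0.27, -0.10 and -1.27 at the same weeks, and fatty acid oxidation -0.94, -1.32, -0.91, -1.17, -0.15, 0.07 and 0.01. Cell cycle genes read 0.80, 0.95, 1.08 and 1.34 from 1 to 4 weeks and 0.02, -0.22 and -0.32 after that. Schwann cell and nerve markers stood at -0.11 at 1 week and at 0.94, 1.13 and 1.28 at 2, 3 and 4 weeks.

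Against control, 3865 genes passed at 1 week (683 higher and 3182 lower, or 494 and 1007 under all 5 scalings), 5260 at 2 weeks (1089 and 4171, or 670 and 1599) and 0 at 6 weeks, where 485 had an unadjusted p under 0.05 and 553 would be due to chance. At 1 week the splits under the other scalings were 1030 and 1650 at a common 75th percentile, 998 and 1319 after quantile normalization, 524 and 1803 as deposited and 1276 and 1108 at a common trimmed mean. At 2 weeks they were 1853 and 2323, 1672 and 2091, 682 and 4475, and 2255 and 1783. With 1 array left out and the spread of the lone array taken from the other groups, 1709 genes passed at 1 week without short-term replicate 1, and 3340 at 2 weeks without short-term replicate 4. At 6 weeks 37 passed without control replicate 4.

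The slope over weeks passed in 3911 genes (3304 positive and 607 negative, of which 474 and 246 under all 5 scalings). Other scalings gave 1051 and 785, 620 and 424, 1327 and 320, and 636 and 842 in the order used above. The steepest positive slopes were those of Gnat3 (1.76 per doubling of time, SE 0.18, adjusted p = 7.3e-04), RT1-Bb (1.02), LOC102554789 (1.00), Sv2b, a protein of synaptic vesicles (0.98, SE 0.31, adjusted p = 0.019), and Fam216b (0.96). The steepest negative ones were those of Tnn, a matrix protein of the tenascin family (-1.83, SE 0.43, adjusted p = 0.013), RT1-Ba (-1.79, SE 0.17, adjusted p = 7.3e-04), Cthrc1 (-1.66, SE 0.36, adjusted p = 0.011), Mx2, a protein induced by interferon (-1.59, SE 0.25, adjusted p = 0.0038), and Col8a1 (-1.36). Both 1-week arrays of Gnat3 lay at the floor, so its slope and its first value depend on the floor, as do the slopes of RT1-Bb with 4 and LOC102554789 with 3 short-term arrays there. Gnat3 read -5.74 against control at 1 week, -5.15 at 2, -3.14 at 3, -1.07 at 4 and -0.42 at 6 weeks, and Mx2 6.22, 4.11, 1.80, -0.18 and 0.75. Tnn lay at the floor on all 4 control and all 4 long-term arrays and at a signal of 807 in short-term muscle. The count of slopes rests on the late arrays: it fell to 391 without long-term replicate 4 (22 weeks) and 2290 without long-term replicate 3 (16 weeks), and to 2 without both. The calls of Cthrc1 (adjusted p = 0.095) and Tnn (0.079) were lost without replicate 4, that of Sv2b without replicate 3 (0.062) or 4 (0.10). Mx2 has 2 probe sets of near equal mean, and its slope lay between -0.25 and -0.83 without arrays whose removal switched to the other.

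**Figure D3:**
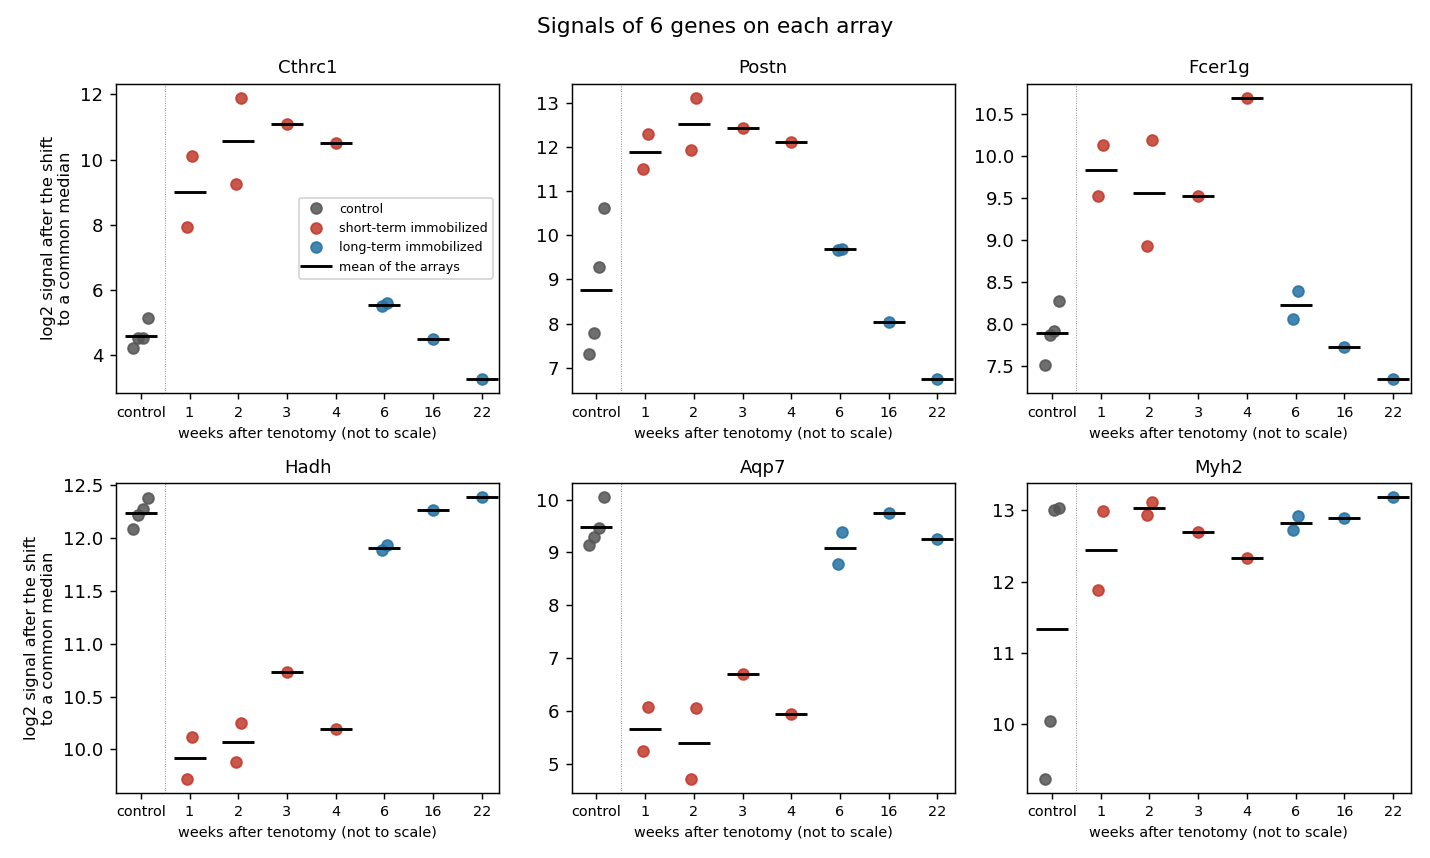
Log2 signal after the shift to a common median of 6 genes on each array, against weeks after tenotomy (not to scale). Points are arrays, coloured by group, and black bars are means of the arrays of a time point: Cthrc1, Postn and Fcer1g were high and Hadh and Aqp7 low on the 6 short-term arrays, and Myh2 was low on 2 of the 4 controls alone.

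The last comparison asks whether long-term muscle kept part of the short-term changes. Across 11064 genes, which are not independent replicates, the log2 changes against control correlated with r = 0.20, and 50.3% of genes had the same sign. Both sets of changes share the 4 controls, which alone makes them correlate. Simulated groups with no change gave r = 0.55, which the group sizes fix, and a covariance of 0.046 ± 0.0017 (SD, 100 simulations). The observed covariance was 0.042. The simulation used 1 spread for all groups and left out that 2 rats gave both muscles, so its covariance is only a rough reference. With the controls split so that each set of changes had its own 2, r was 0.02 as a mean of the 6 splits (from -0.02 to 0.08). The mean covariance was then 0.0056. The r of 0.20 moved with single arrays, to 0.43 without long-term replicate 4, to 0.05 without long-term replicate 1 and to 0.04 without long-term replicate 2.

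**Figure D4:**
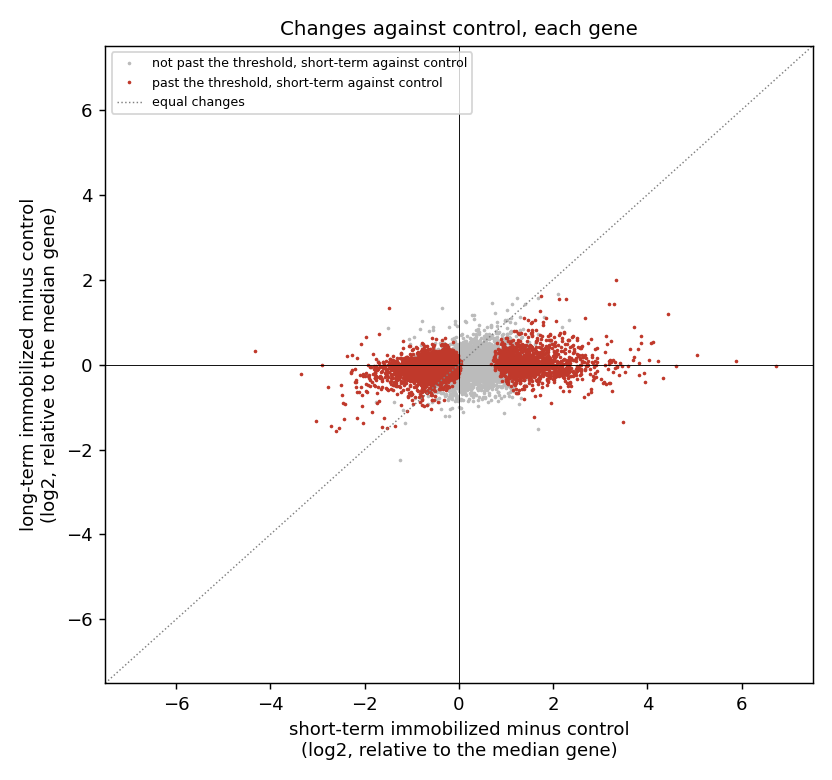
Log2 change against control of each of 11064 genes, relative to the median gene, in short-term (horizontal) and long-term muscle (vertical). Red points passed the threshold in short-term muscle, and the dotted line marks equal changes: the cloud extends along the horizontal axis, from Gnat3 at -4.32 past Cthrc1 at 5.88.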

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

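The 4 tests with other groupings of the arrays were fixed before their results, and the other 6 tests in this part were chosen after the result they concern was seen. The values below stood apart in 1 of 3 ways: an array lay away from the others of its group, a result differed between long-term and short-term muscle, or data were left out of the comparisons.

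An array was tested for lying apart in 360 groups of values, and 26 arrays did so where chance gives about 1 in 20 groups. On the log2 scale the genes were Reep6 on long-term replicate 3 at 8.29 (others 6.3 to 6.63), Stbd1 on control replicate 4 at 9.72, Mmp14 on short-term replicate 4 at 12.2, Ndufs1 on control replicate 1 at 12.3 and on long-term replicate 4 at 12.6, and Ppargc1a on control replicate 3 at 11.3 (others 8.4 to 8.6). Further ones were Cks2 on control replicate 2 at 3.44, RT1-Db1 on long-term replicate 4 at 4.75, Serping1 on the same array at 7.62, Myh3 on control replicate 4 at 10.7, Trim63 on control replicate 3 at 11.2, Ankrd2 on short-term replicate 1 at 10.1, Adipoq on long-term replicate 4 at 5.3, Fam216b on control replicate 3 at 7.34, Acaa2 on control replicate 4 at 11.5 and Sv2b on control replicate 4 at 7.13 (others 11.6 to 12.1). The lists, as mean log2 difference from control, were the denervation response on long-term replicate 1 at 0.355, atrophy ligases on long-term replicate 3 at 0.208, proteasome subunits at 0.0992, chaperones at 0.147 and adipocyte markers at -0.603 on long-term replicate 4, growth factor signalling on control replicate 1 at -0.154 and endothelial markers on control replicate 3 at -0.165. In quality values, the 3' to 5' ratio of Gapdh was 2.78 on long-term replicate 4 (others 1.38 to 1.54), and short-term replicate 4 had a ratio of 3.87 for actin and a 5S rRNA signal of 264 (others 38.4 to 72.9). The causes were not tested.

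Of 83 named genes 72 differed between long-term and short-term muscle, against 6028 of all 11064 genes tested. The rule names many of these genes for passing in this or a related comparison, so the high share follows from the choice. Lower in long-term muscle were, as log2 difference, Tnn at -6.75 (relative to the median gene, from signals of 807 and of 9.69, the floor, where all 4 long-term arrays lay), Cthrc1 at -5.79, RT1-Ba at -4.84, Spon1 at -4.83, C1qtnf3 at -4.65, Cxcl13 at -4.63, Lbp at -4.38, Pamr1 at -4.16, Col8a1 at -4.15, Postn at -4.07, Thy1 at -3.72, Tnc at -3.67, P4ha3 at -3.61, Cpxm1 at -3.57, Mx2 at -3.56 (another probe set -1.53), Mmp14 and Col1a1 at -3.51, Ctsk at -3.40, Igsf10 at -3.25, Myh4 at -3.18, Comp at -2.97, Tnmd at -2.81 and RT1-Db1 at -2.74. So were Cd74 at -2.60, Igf1 at -2.59, Aif1 at -2.54, Cks2 at -2.53, Mki67 at -2.38, Adgre1 at -2.37, Pdgfrl at -2.35, Igfbp4 at -2.34, Fcer1g at -2.33, Serping1 at -2.25, Tgfb1 at -2.23, Cd68 at -2.22, Top2a at -1.87, Col3a1 at -1.79 and Pmp22 at -0.998.

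Higher in long-term muscle were Gnat3 at 4.64 (2 short-term arrays at the floor), Aqp7 at 3.13, LOC102554789 at 2.89, Fam216b at 2.79, RT1-Bb at 2.61 (another probe set -1.59), Pik3c2g at 2.57, G0s2 at 2.49, Amy1 at 2.41, Rbm44 at 2.32, Phf24 at 2.24, LOC100912310 at 2.01, Ndufs1 at 1.72, Ndufa5 at 1.6, Hadh and Ndufb8 at 1.59, Ppargc1a and Acaa2 at 1.52, Stbd1 at 1.5, Pdhx at 1.34 and Reep6 at 1.26. So were Myh1 at 1.20, Hspa9 at 1.14, Hspb3 at 1.12, Padi2 at 1.02, Suclg1 at 0.995, Hk2 at 0.971, Phka1 at 0.874, Fbp2 at 0.866, Ankrd2 at 0.63, Psmd12 at 0.495, Trim63 at 0.455, Psmd1 at 0.382, Myog at 0.377 and Psmb2 at 0.244.

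Among the lists 15 differed by camera. The medians were -2.30 for collagens and extracellular matrix, -1.92 for tendon, -1.89 for macrophage, -1.71 for lymphocyte and antigen presentation and -1.39 for fibroblast markers, -1.61 for matrix proteases, -1.16 for the cell cycle, -0.67 for growth factor signalling and -0.757 for Schwann cell markers. They were 0.964 for fatty acid oxidation, 0.687 for the tricarboxylic acid cycle, 0.467 for the respiratory chain, 0.318 for glycolysis, 0.242 for chaperones and 0.222 for proteasome subunits. None of the 15 was called with an estimated correlation.

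Chance was tested by grouping the arrays in other ways. For short-term against control the real grouping gave 5745 genes and the highest other 3274. Of the 100 groupings taken, the real one included, 1 was as high as the real one, the smallest share this test can give. Chance is thus unlikely but not excluded. For long-term against short-term the values were 6028 and 2313 (1 of 100), and the same holds there. For the trend the real order gave 3911 genes and the highest other order 4009 (2 of 100), which shows only that few orders reach the real count. For long-term against control the real grouping gave 0 genes and the highest other 12. Every grouping reaches 0 (35 of 35), so that test holds no information on chance.

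The fall of fatty acid oxidation genes in short-term muscle was weighed against 3 explanations. RNA of other cells may dilute that of muscle fibres: 35 genes of fibre structure had a median of -0.36 (95% interval -0.58 to -0.25 over resampled genes). That interval holds the arrays fixed and so leaves out the spread between rats. This median fits dilution as part of the cause. A fall of these genes through tenotomy itself would give the same median, so it cannot decide between them. The 35 genes were limited to control signals within the range of the fatty acid oxidation list and at most 6000. The contractile lists lay higher. They were not limited in signal and hold genes above that limit, such as Myh7, so they are no matched comparison and do not weigh against dilution. The slow fibre median was 0.03, with 5 of 11 lower, and the fast fibre median 1.31, with 5 of 15 higher and 2 lower. The fatty acid oxidation median lay 0.66 lower than that of the 35 genes (95% interval 0.41 to 1.10 over resampled genes). This argues against dilution as the whole cause only if tenotomy itself left the structure genes unchanged, which was not tested. The choice of scaling is excluded, as 23 of 25 members were lower under all 5 scalings. A labelling batch or cohort of rats cannot be told apart from tenotomy, since 0 rats gave both a short-term and a control array. Dilution was not tested for the other lists that fell. The respiratory chain median of -0.45 lay within the interval of the structure genes, and the tricarboxylic acid cycle median of -0.70 below it.

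The poly-A spike-ins, which entered no comparison, read 268 on the short-term arrays and 108 on the controls. A brighter hybridisation or scan is excluded, as the hybridisation spike-ins changed by -0.0424 on the log2 scale. Less rat mRNA per amount of total RNA, or another amount of spike-in, fits in direction, since each of the 4 poly-A transcripts was higher. On the log2 scale phe rose by 0.996, lys by 1.075, dap by 1.115 and thr by 1.752, so thr departed from the like fold predicted. The 2 explanations cannot be told apart here, and either may bear on the scaling. Probe sets with no or several symbols were also left out of the comparisons: 1932 of 5227 passed in short-term against control.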

How the results depend on the processing

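The deposited scale, the trimmed mean, leaving out the 2 doubted arrays and leaving out shared probe sets were alternatives chosen after seeing the data, and the others before. For named genes, 2696 results stayed the same over the alternatives other than leaving out single arrays, 97 were weaker, 12 stronger and 1 reversed. For lists 1673 stayed the same, 68 were weaker, 39 stronger and 9 reversed. Where a value moved, the cause was not tested.

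Short-term against control gave 3853 genes (without the control arrays of rats 61 and 62) to 7270 (every probe set), and 4912 (without control replicate 3) to 5954 without single arrays. Long-term against short-term gave 3987 as deposited, and 4857 (without long-term replicate 4) to 6148 without single arrays. Long-term against control gave 1 gene with no filter, 2 with the rat as a fixed replicate block (2 pairs), and 0 without any single array. At 1 week 2317 genes passed after quantile normalization, 2327 as deposited and 2384 at the trimmed mean, with 1709 to 4384 without single arrays. At 2 weeks 3342 passed without the doubted arrays, with 3340 to 5277 without single arrays, and at 6 weeks 4 with no filter, with 0 to 37. The trend gave 1836 genes at the 75th percentile, 1044 after quantile normalization, 1647 as deposited, 1478 at the trimmed mean, 283 without the doubted arrays, 2 without weeks 16 and 22, and 391 to 4749 without single arrays.

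Lists called in long-term against control were 5 with the filter at the 60th percentile, 5 with the mean of probe sets, 7 with every probe set, 12 with the average of time-point means, 6 without the doubted arrays, 10 with the fixed replicate block and 0 with no filter, with fry or with an estimated correlation. Without single arrays they were 2 to 12. An estimated correlation gave 0 lists in the other comparisons too, which gave 15 to 17 and 15 to 16 without single arrays.

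Quantile normalization turned the list median of proteasome subunits to 0.0323 in short-term against control and -0.0309 in long-term against short-term, and ribosomal proteins had 0.16 and -0.19 with it and -0.11 at the trimmed mean, where the direction of the test changed. Array weights turned Myog to 0.0310 in short-term against control and the matrix list to 0.18 in long-term against control. Without the doubted arrays the long-term medians were 0.24 for the matrix list, 0.24 for fibroblast and -0.0269 for tendon markers, and without long-term replicate 4 alone 0.18 for macrophage markers, 0.24 for the matrix and -0.0269 for tendon. Without long-term replicate 2 they were -0.29 for the matrix list, -0.48 for macrophage and -0.42 for fibroblast markers, and without replicate 1 -0.96 for tendon markers.

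The correlation of both sets of changes was 0.43 with array weights, 0.0406 with time-point means, 0.37 without the control arrays of rats 61 and 62, 0.46 without the doubted arrays, 0.0208 with split controls, and 0.0410 to 0.43 without single arrays. With the rat as a random replicate block it was 0.22, the correlation within a rat being estimated at 0.113, and 5812, 0 and 6023 genes passed. No random block was fitted for the trend, since each tenotomized array came from another rat.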

Other observations

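All tests in this part were chosen after the result they concern was seen. Adipocyte and lipid genes moved both ways in short-term muscle. Scd and Fasn, enzymes that make fatty acids, were higher by 3.71 (adjusted p = 3.0e-04) and 2.08 (adjusted p = 4.1e-04) on the log2 scale, while Plin4, a coat protein of lipid droplets, was lower by -2.28 (adjusted p = 3.2e-06). Odc1 and Sms, enzymes of polyamine synthesis, were lower by -1.34 and -0.98, and Arg1 was higher by 1.46. In the clock list Cry1 was lower by -0.66 and Hlf by -0.89. Runx1 and Hdac4, transcription regulators that rise after denervation, were higher by 2.04 (adjusted p = 0.0018) and 2.01 (adjusted p = 0.0025), the 2 members of 11 in the denervation list that rose, while 3 were lower and the list did not pass (adjusted p = 0.36). These genes were named after their values were seen.

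Some markers had their own time course. Mbp read 0.20 against control at 1 week and 2.46, 2.52 and 2.62 at 2, 3 and 4 weeks. Myh4 read 4.23, 2.66, 2.48 and 0.90 from 1 to 4 weeks. Fbxo32 read 1.20 at 1 week and -1.02 at 2 weeks. No test between time points was run for these.

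In rats 61 and 62, which gave a control and a 6-week muscle each, some genes were high in 1 rat and low in the other. Inherited differences between outbred rats are a candidate explanation. Genes with 2 levels were sought in the other 10 arrays, which include the short-term ones. Among 13 genes with levels at least 2.5 apart on the log2 scale, 4 fell into pairs by rat at the midpoint of the levels and 0 crosswise. The 13 include Aqp7, C1qtnf3, Col1a1, Cthrc1, Postn, RT1-Bb, Spon1 and Tnn, which differed between long-term and short-term muscle. Of the 4 that fell into pairs by rat, Grm4, RT1-T24-4 and Sv2b were high in rat 62 and low in rat 61. The other, Col1a1, read 10.4 to 10.7 on all 4 arrays and so does not divide the rats. So few genes leave the explanation open. Across all genes, the deviations of these arrays from their group means were correlated between arrays. Pairs of the same rat gave r = 0.21 and 0.41, and crossed pairs -0.08 and -0.03.

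Targets of ATF4, a transcription factor of the stress response to lack of amino acids, varied between arrays. The mean log2 signal of Asns, Phgdh, Psat1, Mthfd2, Trib3 and Fgf21 was 8.65, 8.83, 9.27 and 4.01 on the controls, 4.72 to 5.93 on the short-term arrays and 4.35, 5.68, 8.70 and 8.23 on the long-term arrays. A shared programme predicts that other targets follow within groups. For 33 others the median correlation with these 6 was 0.82, at percentile 100 of 10000 random lists (median 0.10), which is consistent with a shared programme. With control replicate 4 and long-term replicate 1, both of rat 61, left out of the correlation it was 0.66, still at percentile 100. The group means were still taken with both arrays, so this does not remove their effect. In short-term against control 23 of the 33 were lower and 2 higher, 15 and 2 of them under all 5 scalings. What sets the level on each array was not tested. The control and 6-week muscles of rat 62 read 8.65 and 5.68, and those of rat 61 read 4.01 and 4.35. Both muscles of a rat shared its feeding, so feeding alone cannot account for the difference within rat 62, which is 1 rat. Measuring ATF4 protein in muscles with recorded feeding before death would test a nutritional cause of differences between rats.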
